A study of Mus musculus with 6 samples.

How the data were processed

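RNA of a MyoD-silenced C2C12 clone and of C2C12 control cells was compared at days 1, 3 and 6 of differentiation on 6 arrays, 2 per day with the dyes exchanged. Per the labels' protocols, RNA was purified with Trizol, reverse transcribed and labelled with a tyramide amplification kit, and hybridised to a muscle array made for human genes. The deposited values are a score per spot, and how the authors filtered, normalised or scaled them is not given in the sources used here. The scores were centred near 0 on every array with SDs of 1.41 to 1.62. Of all values, 2 lay beyond 16, with the largest at 21.6, more than a log2 ratio of a 16-bit scanner can reach, so the scores were not read as log2 ratios. How binding of mouse RNA to human probes affects the scores was not tested.

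The design fixed before the data were examined assumed log2 ratios and thresholds of 2-fold. With scores these were replaced by 2 score units on both arrays of a day, a threshold chosen after the distribution of values had been seen. The planned treat test and the 1.5-fold threshold need a log scale and were not run; 1 and 1.5 units were added instead. There were 0 missing values, so the planned filters on missing arrays change nothing.

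Spots with odd and following even numbers were duplicates: in 1743 of 1743 named pairs both spots had the same gene symbol. They were averaged to 2688 probes. A platform annotation table gave 1 gene symbol for 3486 spots, several for 0 and none for 1890. Probes of a gene were averaged, and 144 genes had more than 1 probe. The first 2 probes of these genes correlated across genes at 0.18, 0.28 and 0.09 on days 1, 3 and 6, against 0.115, 0.000398 and 0.0662 for 1 draw of random pairs, so on days 1 and 6 they agreed little better than random pairs. The 2466 features were centred on the median of each array. Symbols are human, and no genome coordinates were used. Duplicate spots correlated at 0.25 to 0.60 within arrays, and probes 2 places apart in spot number at 0.11 to 0.38, against -0.02 to 0.14 for adjacent probes, a dependence on position that is not corrected in the values reported.

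The shared change was tested with limma 3.58.1 in R 4.3.3 on the 3 day means (an intercept against 0, two-sided, Benjamini-Hochberg, threshold 0.05). No test was made within a day; counts of features at least 2 units from 0 in the same direction on both arrays are given. A limma fit of the 6 arrays with the 3 days as coefficients gives adjusted p against array spread only. Of 14 lists fixed before the data were examined, 10 had at least 5 measured genes and were tested with camera (preset correlation 0.01), with an estimated correlation and fry beside it. Tested on simulated data with 2466 features and 200 changed in each of 5 runs, the shared test recovered 92% of changes of 2 units and 100% of 4 units, with 3.32% false calls. A simulated list shift of 1 unit was called in 5 of 5 runs, and unshifted lists in 0 of 45 tests. The simulated noise was normal, independent between features and scaled by limma's moderated SDs. In the data few features passed and probes 2 places apart correlated, so these rates need not apply to them. There S100A11 at -2.05 and DUSP26 at -2.04 did not pass, while CCDC124 at 2.11 did.

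The genes named follow a rule fixed before the data were examined. They are MYOD1 and the 3 title genes; for the shared change the 10 highest and 10 lowest means past the threshold, filled up by size among genes with the same sign on all 6 arrays; per day, and for the change from day 1 to day 6, the 5 highest and 5 lowest among the genes counted; and per list the 3 highest and 3 lowest members. Alternatives were 6 separate arrays, a dye term, values as deposited, scale normalization by median absolute values, separate probes, a robust prior (statmod 1.5.0), other thresholds, and leaving out each array and each day. Alternatives chosen after seeing the data were the subtraction of the median of 10 neighbouring probes, the median of a gene's probes, genes only, and leaving out the first 40 spots. The 10 neighbours lay at even places from 2 to 10 on either side in probe order, so adjacent probes were not among them. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.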

Results

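The study compared a MyoD-silenced clone with control cells of the mouse myoblast line C2C12, which fuses into myotubes when serum is lowered. MyoD is a transcription factor that commits cells to the muscle lineage, and the clone, MyoD(-)cl.A8, carried a construct transcribing MyoD in antisense. RNA of clone and control was compared at 1, 3 and 6 days of differentiation on a 2-colour muscle array built for human genes. Gene names are those of the human probes. Whether the mouse RNA bound by a probe, such as that of HMGN4, came from the gene of that name was not tested. Each day had 2 arrays with the dyes exchanged, called replicate A and replicate B here, which made 6 arrays in all. A day's arrays compared the same cell types with crossed dyes and were counted as 1 replicate, so n = 3 days and each day alone had no replicate. Each array gave 5376 spots, or 2466 features after averaging, of which 1521 were genes and 945 were probes without a gene name. Spot intensities were not used here, so signal over background is unknown, and the number of arrays limits the precision.

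Values are scores whose scale, centring and direction are not stated, and no fold changes are given. Array medians over the features lay between -0.07 and 0.03. Positive values are taken as higher in the silenced clone, a direction that is likely, since the labels call the clone the test and the control the reference. Arrays of the same day correlated across features at 0.16 to 0.21, against -0.08 to 0.12 for arrays of different days, so both arrays of a day were read in the same direction. Features are not independent replicates. Except for camera, p-values come only from the spread between these samples, which may be technical, and 1 clone was used. Camera sets a list's genes against the other genes, so its p-values also rest on the spread between genes. In limma each feature's variance is moderated toward that of all features. Its p-values therefore do not rest on a gene's printed SD alone.

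The silenced gene and the genes of the series title were examined first, to ask whether they differed between clone and control. MYOD1 (Entrez Gene 4654) had a mean score of 0.15 ± 0.20 (SD, n = 3 days), with limma's adjusted p = 0.983. The strand bound by its probe is not given in the sources used here, and the construct itself is transcribed from MyoD sequence, so this value does not check the silencing. S100A6 (Entrez Gene 6277), the calcium-binding protein calcyclin, fell in the clone, with a mean of -4.70 ± 2.26 (SD, n = 3 days) and limma's adjusted p = 0.000698. Its score was below 0 on 6 of 6 arrays, with day means of -2.12, -6.38 and -5.59. CDKN1C (Entrez Gene 1028), the cyclin-dependent kinase inhibitor p57, stood at -6.97 and -8.53 on the day 1 arrays, at 1.80 and -0.58 on day 3 (mean 0.61) and at 1.76 and -0.54 on day 6 (mean 0.61). Its mean over the days, -2.18 ± 4.83, did not pass limma's test (adjusted p = 0.731), and was 0.61 without day 1 and -3.57 without day 3 or day 6. ANKRD2 (Entrez Gene 26287), an ankyrin repeat protein of striated muscle, averaged 0.06 ± 0.45 (adjusted p = 0.990 in limma). Each of these genes had 1 probe in 2 spots. Of the 3 title genes, 1 passed over all features and 1 adjusted over the list alone; because the study named these genes itself, the count is not independent evidence.

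**Figure D1:**
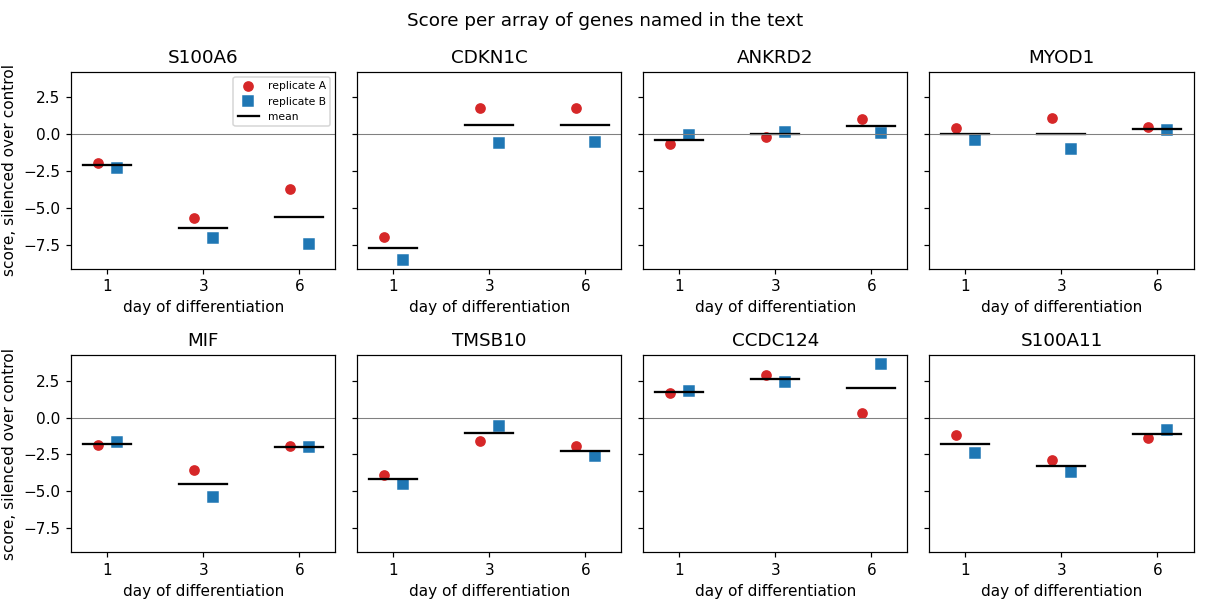
Score of the silenced clone over control (vertical axis, score units, likely direction) by day of differentiation for 8 genes, with replicate A as circles, replicate B as squares and the day mean as a line. S100A6 lay below 0 on 6 of 6 arrays, and CDKN1C stood at -6.97 and -8.53 on day 1, while its later arrays had opposite signs within each day.

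The shared change asked which genes differed from control in the same direction over the 3 days. Besides S100A6, MIF, a secreted inflammatory cytokine, fell with a mean of -2.74 ± 1.51 and limma's adjusted p = 0.0278. TMSB10, an actin-sequestering thymosin, fell with a mean of -2.52 ± 1.58 (adjusted p = 0.0458). CCDC124, a coiled-coil protein, rose with a mean of 2.11 ± 0.46 (adjusted p = 0.0458). These 4 genes had the same sign on 6 of 6 arrays. In all, 9 of 2466 features passed, 5 higher and 4 lower, against 164 at an unadjusted p under 0.05. The other 5 were probes without a gene name, of which 4 higher ones lay in a run of 11 neighbouring probes with means of at least 1 unit. The run averaged -0.03 on the day 3 replicate B. Outside that run too, means of probes 2 places apart correlated, at 0.227, while those of adjacent probes correlated at 0.0550.

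**Figure D2:**
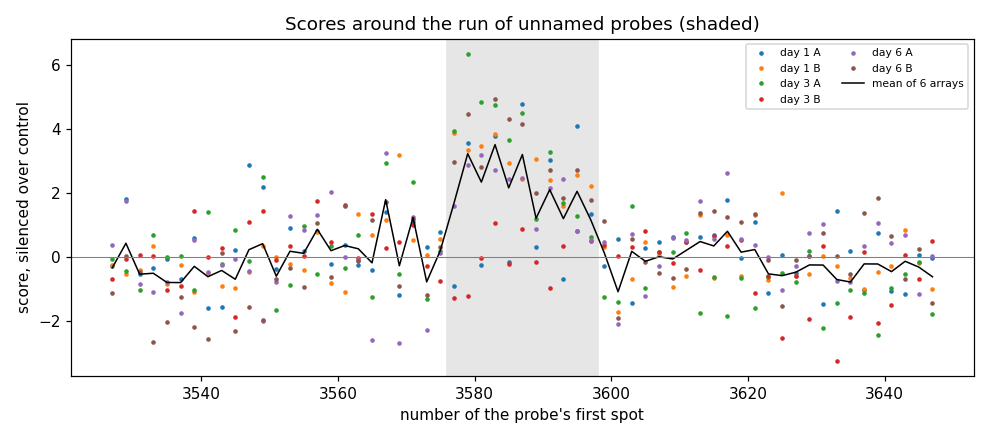
Score of the silenced clone over control (vertical axis, score units) against the number of a probe's first spot (horizontal axis), with points for each of the 6 arrays, a line for their mean and the run of 11 unnamed probes shaded. The run averaged 2.17 over the arrays and -0.03 on the day 3 replicate B.

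Further genes had the same sign on 6 of 6 arrays without passing, and the 7 lowest and 9 highest by mean are named here. On the lower side these were S100A11, another S100 calcium-binding protein, at -2.05 (adjusted p = 0.0870), ARHGAP33 at -2.10, DUSP26 at -2.04, IGFBP7 at -1.82, PGK1 at -1.76, CKMT2 at -1.64 and TNFAIP2 at -1.63. On the higher side were YPEL3 at 2.33, USP24 at 1.89, AKIRIN2 at 1.79, SAMM50 at 1.72, NEURL1 at 1.69, TOB2 at 1.68, UBB at 1.67, HSPB1 at 1.61 and COMTD1 at 1.49. Some of them passed in limma under an alternative. S100A11 did with 6 separate arrays (0.0482), and DUSP26 with separate probes, by the lower adjusted p of its 2 probes (0.00647). Without day 1 these were S100A11 (0.0396), DUSP26 (0.00200), YPEL3 (0.00402), USP24 (0.0144), ARHGAP33 and CKMT2 (0.0296 for both). Some means rested on 1 array or day. YPEL3 stood at 9.11 on the day 3 replicate B, and its mean was 0.96 without that array, 3.70 without the day 3 replicate A and 0.99 without day 3. UBB had 0.91 without the day 1 replicate A and 1.07 without day 1, and COMTD1 0.90 without the day 6 replicate B or without day 6. ARHGAP33 had -1.35 without the day 3 replicate B, and IGFBP7 -1.19 without day 1. As deposited, without centring, 12 features passed (8 higher, 4 lower). The call of S100A6 ended without the day 3 replicate A (adjusted p = 0.280), the day 6 replicate A (0.0751), day 3 (0.280), day 6 (0.647) or with a robust prior (0.0762), while its mean stayed between -5.99 and -3.86 under all alternatives. MIF passed without day 1 (0.000379) and without the day 6 replicate B (0.0460) but not with any other array or day left out (0.0681 to 0.744). CCDC124 passed only without day 1 (0.0207; the others 0.0805 to 0.744), and TMSB10 with no array or day left out (0.103 to 0.776; mean -1.68 without day 1). Both also missed the threshold with scale normalization, separate probes, neighbouring probes subtracted, genes only or without the first 40 spots (0.0503 to 0.118), and TMSB10 with a robust prior (0.0616).

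Day 1 asked what differed early. CDKN1C was lowest, with a mean of -7.75. TMSB10 (-4.21), IGFBP7 (-3.08), a secreted binder of insulin-like growth factors, and ATOX1 (-2.25), a copper chaperone, were also at least 2 units lower on both arrays. HMGN4 (3.97), a nucleosome-binding protein, BSG (3.86), the membrane glycoprotein basigin, DYNC1I2 (3.31), a dynein chain, and HSPE1 (2.48), a mitochondrial co-chaperonin, were at least 2 units higher on both. With neighbouring probes subtracted, DYNC1I2 (1.61 on replicate B) and ATOX1 (-1.39 on replicate A) no longer reached 2 units on both arrays, and without replicate A DYNC1I2 stood at 2.03. These 8 genes were the named part of 20 features (13 higher, 7 lower), and 2 features were at least 2 units apart from 0 with opposite signs on the arrays. By the same threshold, pairs of arrays of different days shared 10 to 24 features with opposite dyes and 12 to 28 with the same dyes. The day 1 count lay within these ranges, and those of day 3 (31) and day 6 (45) lay above them. With 1 RNA pair there is no test of the day. A limma fit of the 6 arrays, whose error is only the spread between dye-swapped arrays, called 6 features, among them CDKN1C (adjusted p = 0.000123), TMSB10 (0.00703), HMGN4 (0.0314) and BSG (0.0314). With a dye term added it called 2 features. CDKN1C passed (limma's adjusted p = 0.00046), but TMSB10 (0.0527), HMGN4 (0.0621) and BSG (0.155) did not.

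On day 3, S100A6 (-6.38), PALM (-5.23), a membrane phosphoprotein, MIF (-4.49), MYH7 (-3.66), the slow myosin heavy chain, and S100A11 (-3.27) were the lowest genes at least 2 units lower on both arrays. Among genes at least 2 units higher on both arrays, the highest were PPP1R14B (5.56), a phosphatase inhibitor subunit, TRIM54 (3.38), a sarcomere-associated ubiquitin ligase, CHCHD2 (2.88), a mitochondrial protein, the metallothionein MT2A (2.82) and SUGT1 (2.80), a co-chaperone. In all, 31 features counted (11 higher, 20 lower; 10 and 14 of them genes), and 6 had opposite signs. The limma fit against array spread called 8 features, among them S100A6 (adjusted p = 0.00223), PALM (0.00253), MIF (0.00365), PPP1R14B (0.00365), MYH7 (0.0145), TRIM54 (0.0266) and S100A11 (0.0430). With a dye term added it called 4 features, S100A6, PALM, MIF and PPP1R14B. MYH7 (limma's adjusted p = 0.0682), TRIM54 (0.0911) and S100A11 (0.137) then did not pass.

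On day 6, S100A6 (-5.59), CES1 (-4.71), a carboxylesterase, NUB1 (-4.04), a regulator of the ubiquitin-like protein NEDD8, the ribosomal protein RPL17 (-3.79) and HMGN4 (-3.14) were the lowest genes at least 2 units lower on both arrays. Without replicate B, S100A6 stood at -3.72. Among genes at least 2 units higher on both arrays, SHISAL2A (2.61), the ATP synthase subunit ATP5MC2 (2.40), AKIRIN2 (2.39), the elongation factor EEF1G (2.32) and TRDN (2.24), a sarcoplasmic reticulum protein, were highest. The count was 45 features (17 higher, 28 lower; 5 and 15 of them genes), with 10 of opposite signs. With neighbouring probes subtracted, 4 of these 5 higher genes no longer reached 2 units on both arrays: ATP5MC2 (mean 1.11), TRDN (1.94), EEF1G (1.97) and AKIRIN2 (2.15). The limma fit against array spread called 7 features, all lower, among them S100A6 (adjusted p = 0.00623), NUB1 (0.0154), CES1 (0.0401) and RPL17 (0.0401). With a dye term added it called 1 feature, S100A6 (limma's adjusted p = 0.0406), and not NUB1 (0.0574), RPL17 (0.0754) or CES1 (0.184). Counts at other thresholds, and on single arrays, differed by more than 1.5 times from those of each day.

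**Figure D3:**
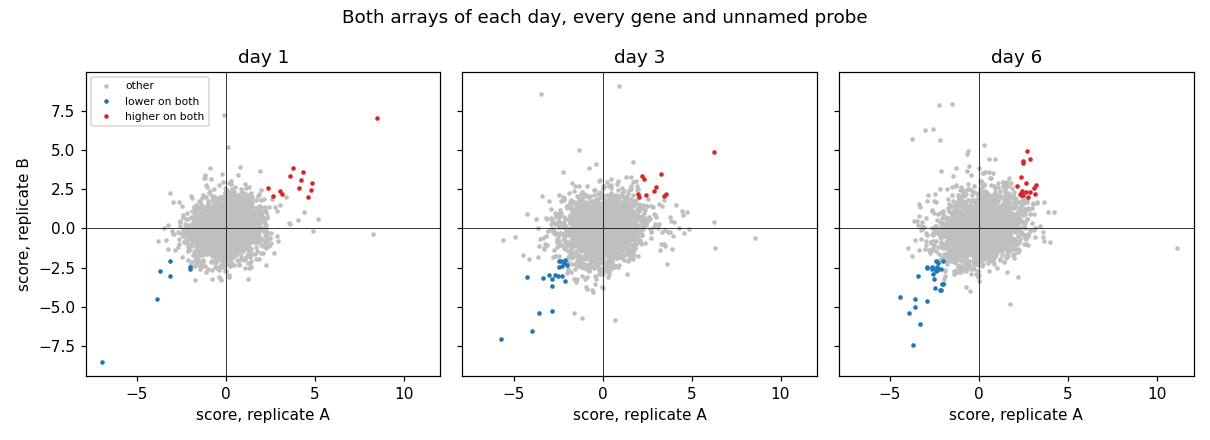
Score on replicate A (horizontal axis, score units) against replicate B (vertical axis, score units) for 2466 features on each day; coloured points lay at least 2 units from 0 in the same direction on both arrays. There were 20, 31 and 45 such features on days 1, 3 and 6.

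The change from day 1 to day 6 asked which differences between clone and control moved as differentiation went on. CDKN1C moved up by 8.36. The glycolytic enzyme PGAM2 went from -2.17 to 1.84 and the fast troponin TNNI2 from -1.80 to 1.57, while ATOX1 moved up by 3.96 and the tubulin TUBB4B by 3.75. Toward lower scores, HMGN4 went from 3.97 to -3.14 and RPL17 from 2.25 to -3.79, while BSG moved by -5.60, DYNC1I2 by -5.08 and NUB1 by -4.80. For 45 features (15 upward, 30 downward; 10 and 16 of them genes) all 4 differences between a day 6 array and a day 1 array reached 2 units in 1 direction. An unnamed probe at spots 4045 and 4046, picked out after its values were seen, went from 7.77 to -4.42. The limma fit against array spread called 9 features, of which 6 were genes: CDKN1C, HMGN4, RPL17, BSG, DYNC1I2 and NUB1, with adjusted p from 0.00125 to 0.0411. With a dye term added it called 5 features.

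Gene lists fixed before the data were examined asked whether groups of genes shifted together over the days. Of 62 genes of oxidative phosphorylation, 47 had a mean above 0 and 15 below, and the list rose with a mean score of 0.32 (camera in limma, adjusted p = 0.00236 over 10 lists), a call that ended with an estimated correlation (adjusted p = 0.463). Its highest members were ATP5MC3 (1.58), ATP5MK (1.25) and NDUFS1 (1.17), and ATP5MG stood lowest at -1.18. By day, ATP5MK stood at -0.51, 2.97 and 1.31, and ATP5MG at -0.87, 0.17 and -2.83. None of the 62 passed singly, over all features or adjusted over the list alone. The S100 family fell as a list of 8 genes (mean -0.93, camera's adjusted p = 0.00997, and 0.463 with an estimated correlation). The fall was carried by S100A6 and S100A11, which passed adjusted over the list alone. Of the members, 4 lay above 0 and 4 below, and the median was -0.18. S100A6 is also a title gene of the study, so this fall is not independent evidence. Neither call held in fry, which asks whether a list's genes move on balance one way (adjusted p = 0.336 for both). The setting with an estimated correlation also raised p where that correlation lay under the preset 0.01. Muscle energy genes, at 0.0097, went from an unadjusted p of 0.0475 to 0.185 in camera. Calls lost in that setting therefore do not show that correlation between genes made them. Without day 3 the adjusted p was 0.0684 for oxidative phosphorylation and 0.231 for the S100 family; without the day 6 replicate B these were 0.0504 and 0.116, and without the day 3 replicate B the S100 family had 0.0604.

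The other 8 tested lists did not pass, though 2 of them did under an alternative. Muscle energy genes averaged -0.28 over 21 genes (adjusted p = 0.138) and passed without day 6 (-0.42, 0.0487), but averaged -0.13 without day 1 and -0.16 with separate probes; 3 of them passed adjusted over the list alone: PGK1, CKMT2 at -1.64 and the adenylate kinase AK1 at -1.48. Stress chaperones averaged 0.30 over 17 genes (0.138) and passed with separate probes (0.40, 0.0173), but averaged 0.15 without day 3, with HSPE1 at 1.94 and the small heat shock protein HSPB1 at 1.61 passing adjusted over the list alone. Excitation and contraction coupling genes averaged 0.25 over 13 genes (0.239), with 11 above 0, but 0.10 without the day 3 replicate A or with neighbouring probes subtracted, and 0.41 without the day 3 replicate B. Sarcomere genes averaged -0.03 over 42 genes (0.797), from LDB3 and MYH7 at the low end to TRIM54 at the high end. Myogenic regulators averaged -0.22 over 7 genes (0.369), but -0.02 without the day 6 replicate A, -0.43 without the day 6 replicate B, -0.34 without the day 3 replicate A, -0.11 without the day 3 replicate B, -0.35 without day 3 and -0.10 with neighbouring probes subtracted. Extracellular matrix genes averaged 0.04 over 13 (0.797), cytosolic ribosomal proteins -0.03 over 54 (0.797), and proteasome and ubiquitin genes 0.22 over 11 (0.369), where UBB at 1.67 passed adjusted over the list alone and the list mean was 0.10 without day 3. Lists of under 5 measured genes were not tested. Of 2 cell cycle genes, H2AZ1 stood at -1.56 and passed adjusted over the list alone, but not over all features (limma's adjusted p = 0.240). PGK1, CKMT2, AK1, HSPE1, HSPB1 and UBB did not pass over all features either (0.104 to 0.278 in limma). Passes over a list alone are not adjusted for the number of lists. Of the 2 genes of cell cycle exit, CDKN1C and CCND3, and of the 4 markers of other lineages, TAGLN, CNN1, FABP4 and SCD, none passed.

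**Figure D4:**
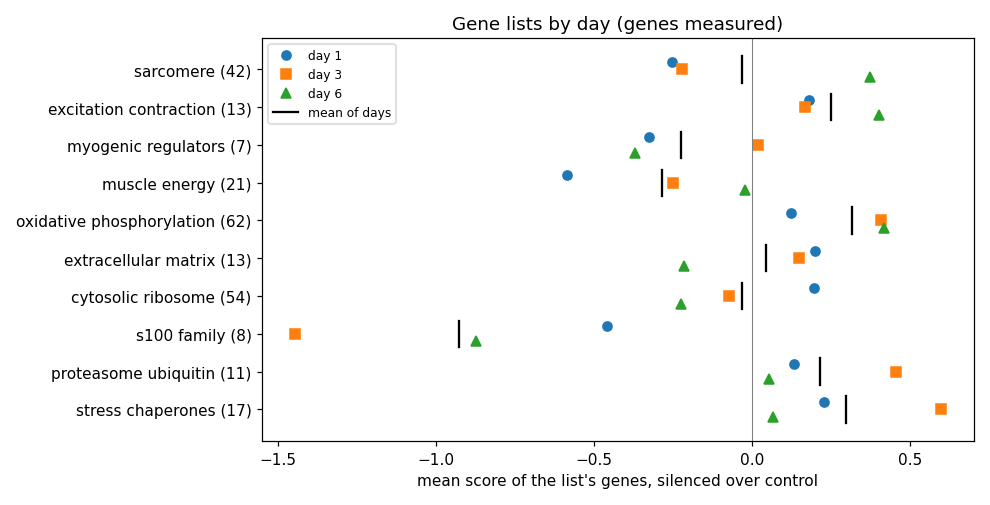
Mean score (horizontal axis, score units, silenced over control) of the genes of each of 10 lists on days 1, 3 and 6, with the mean of the days as a black line and the number of measured genes in brackets. The S100 family lay at -0.93 and oxidative phosphorylation at 0.32.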

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

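The tests of dye bias, of a single spot and of position for the run of unnamed probes were chosen after the results were seen; the position tests for CDKN1C and S100A6 and the splits were chosen before. All differences of single features between days were tested with limma against the spread between dye-swapped arrays only.

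Differences between days passed that test for 7 other named genes and for CDKN1C. From day 1 to day 3, CDKN1C moved by 8.36 (adjusted p = 0.00375), PALM by -6.08 (0.0160) and PPP1R14B by 6.19 (0.0441). From day 1 to day 6, CDKN1C moved by 8.36 (0.00125), HMGN4 by -7.12 (0.00294), RPL17 by -6.04 (0.0157), BSG by -5.60 (0.0203), DYNC1I2 by -5.08 (0.0411) and NUB1 by -4.80 (0.0411). PPP1R14B moved by -7.38 from day 3 to day 6 (0.0269). With a dye term added, the fit called 0 features from day 3 to day 6, so that PPP1R14B no longer passed there. From day 1 to day 3 the term took the count from 4 to 2, and from day 1 to day 6 from 9 to 5.

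CDKN1C was low on both day 1 arrays, and later stood at 1.80 and -0.58 on day 3 and 1.76 and -0.54 on day 6. A dye effect equal on both arrays cancels in the day 1 mean of -7.75 (difference of replicates A and B divided by 2, 0.78), which argues against dye bias. The median of the 10 neighbouring probes was -0.64 on the lower of the day 1 arrays. It argues against an effect of position shared with these probes, which did not include the adjacent ones. The highest of the 4 spot values was -6.42, which argues against a defect of a single spot. What stays open is the silencing itself, other differences of this single clone from its control, and chance differences between the RNA pairs of the days, none of which was tested; an early loss of CDKN1C in the silenced clone is a hypothesis.

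S100A6 was low on 6 of 6 arrays. Its mean of -4.70 held both dye orientations equally (difference of replicates divided by 2, 0.89), which argues against dye bias. This reading needs both arrays of a day to run in the same direction, and their correlations of 0.16 to 0.21, with opposite dyes, argue against columns running red over green. The median of the 10 neighbours of S100A6 was -0.25 on the lowest array. It argues against an effect of position shared with these probes, which did not include the adjacent ones. The silencing may lower S100A6, as may any other difference of the clone; binding of mouse RNA from related S100 genes to the human probe was not tested.

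A run of 11 unnamed probes between spots 3577 and 3598 averaged 2.17 over the 6 arrays, but -0.03 on the day 3 replicate B, and held the 4 unnamed probes that passed as higher over the days. Its means of both dye orientations were 2.30, 1.62 and 2.58 on days 1, 3 and 6. The SDs over the probes were 1.12, 0.88 and 0.92. The run was picked by its mean over the 6 arrays, so these means cannot decide on dye bias. The difference of replicates divided by 2 was -0.58, 1.65 and -0.57. On day 3 the run thus rested on replicate A, and an effect of that array or of its dyes stays open. Position on the slide may contribute: outside the run, means of probes 2 places apart correlated at 0.227 but those of adjacent probes at 0.0550, which does not decide it. Related sequences of probes printed next to each other were not tested, and no biological explanation was tested.

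The count of 9 features over the 3 days was set against other splits of the days by sign. Of the 4 splits, 1 gave as many, the real one, and the highest of the others gave 0. With 4 splits the share cannot fall under 0.05.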

How the results depend on the processing

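Thresholds in score units, subtraction of neighbouring probes, genes only, the median of probes and leaving out the first 40 spots were chosen after the data had been seen. For the 9 features of the shared change, counts were 5 with the replicate block (a dye term; S100A6 and MIF were among them, while TMSB10 and CCDC124 had adjusted p = 0.0712), 29 without day 1, 0 without day 3, 0 without day 6, 4 with neighbouring probes subtracted and 2 with genes only; leaving out single arrays gave 0 to 8. The letters A and B marked the same dye orientations on every day. Differences of replicates A and B correlated between days at -0.002, -0.012 and -0.038. Across the features as a whole, no dye effect shared between days was therefore seen. Day counts of 20, 31 and 45 became 177, 204 and 268 at 1 unit, 46, 79 and 113 at 1.5 units, 50, 97 and 111 for the mean of the arrays, 6, 8 and 7 in the limma fit against array spread, and 2, 4 and 1 with the replicate block added, which left CDKN1C on day 1, S100A6, PALM, MIF and PPP1R14B on day 3 and S100A6 on day 6 as named genes. On single arrays they were 136 to 154, 211 to 216 and 236 to 249. The change from day 1 to day 6 went from 45 features to 237 for the difference of day means, 233 at 1 unit, 9 in the limma fit and 5 with the replicate block; single arrays left out gave 149 to 215. For the day counts and the change from day 1 to day 6, moves with other thresholds or fewer arrays follow from these settings. The replicate block leaves the day means unchanged, since each day holds both dye orientations, so its moves lie in the error of the fit. The cause of the other moves, among them those in the limma fit, was not tested. The 2 list calls became 0 with an estimated correlation, 0 with fry and 0 without day 3, and 0 to 2 with single arrays left out. With neighbouring probes subtracted, HSPE1 (2.21), TMSB10 (-3.58) and IGFBP7 (-2.82) on day 1 and TRIM54 (3.18) on day 3 moved by more than the SD of their arrays. Values near 0 changed sign. With single arrays left out, MYOD1 ran from -0.21 to 0.50, ANKRD2 from -0.10 to 0.22, sarcomere genes from -0.105 to 0.040 and ribosomal proteins from -0.080 to 0.016. With days left out, ANKRD2 was -0.17 without day 6, sarcomere genes 0.077 and 0.062 without day 1 or day 3, extracellular matrix genes -0.032 and -0.0085 without day 1 or day 3, and ribosomal proteins 0.063 without day 6; without moving across 0, sarcomere genes were -0.24 without day 6, extracellular matrix genes 0.17 without day 6 and ribosomal proteins -0.15 without day 1. CDKN1C had a mean of 0.61 without day 1. Leaving out an array of a day moves that day's gene values by less than their SD by construction, so it says nothing of their stability. The treat test and the 1.5-fold threshold were not run. Signal over background is unknown here and limits what can be said of weak spots.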

Other observations

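Sarcomere genes had list means that varied by day. Over 42 genes the mean score was -0.25 on day 1, -0.22 on day 3 and 0.38 on day 6. The median on day 6 lay at the percentile 99.6 of 10000 random lists. This was not the highest among the 10 lists: oxidative phosphorylation lay at 99.98 on days 3 and 6. The random lists were not matched on expression or on correlation between genes, so such percentiles are not tests. The difference of 0.63 from day 1 to day 6 had an unadjusted p = 0.00495 in camera, run on the 6 arrays. Each day had 1 RNA pair, so camera took dye-swapped arrays as replicates and did not measure the spread between RNA samples. The adjusted p was 0.0495 over the 10 lists of that pair of days and 0.148 over the 30 tests of 10 lists and 3 pairs of days, a wider adjustment chosen after the first value had been seen. With an estimated correlation it was 0.390 over the 10 lists and 0.719 over the 30 tests, so whether the difference passed depends on these choices. Without the first 40 spots, which hold abundant muscle genes, the difference was 0.67, and with neighbouring probes subtracted it was 0.38 (unadjusted p = 0.0923). On the day 6 arrays the list mean was 0.16 and 0.59. These comparisons between days were added after the data had been seen.

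Muscle energy genes had a median on day 1 at the percentile 1.07 of random lists, with PGAM2 at -2.17 that day, and at 36.0 and 88.1 on days 3 and 6. Their difference between days 6 and 1 was 0.56 over 21 genes. In camera, again with dye-swapped arrays as replicates, it had an unadjusted p = 0.0462. It did not pass over the 10 lists (camera's adjusted p = 0.154) or the 30 tests (0.289).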
